A study of Mus musculus with 8 samples.

How the data were processed

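The deposited table holds gene-level counts from RNA-seq of MLO-Y4 cells, 4 libraries from non-irradiated and 4 from laser-irradiated cells, each from poly(A)-enriched RNA per the labels' protocols. Per the submitters' processing notes, the tools named are Trimmomatic 0.39, FastQC 0.11.9, HISAT2 2.2.1, StringTie 2.1.7 and DESeq2 1.32.0 with the genome build GRCm39. Their order, their settings, the annotation release, the read length and whether counting used strand are not given in the sources used here. Overlapping and antisense genes, and near-identical paralogs such as Hspa1a and Hspa1b or Actb and Actg1, are therefore uncertain.

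The values the authors deposited are whole-number estimated counts, not normalized, and no rounding was needed. They do not behave as counts of single reads. Among genes with a mean of 5 to 100 counts the median ratio of variance to mean was 4.16 in non-irradiated and 4.19 in irradiated libraries. The values 4 and 8 also occur more often than their neighbours, clearly so for 4 (6096 values of 4 against 4006 of 3 and 2428 of 5). The peak at 8 is slight (2551 against 2515 of 7 and 1549 of 9). The value 1 is the most frequent of 1 to 9 (6623), which steps of exactly 4 would not give. From the variance and the peak at 4, a fragment may add about 4 counts. Counting error is then larger than a Poisson count of the same size would have. Within a group, pairs of libraries differed by 6.62 to 9.58 times the Poisson expectation, which with about 4 counts to a fragment does not settle whether any were repeats of one culture.

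The columns are numbered 5 to 8 in each group and the sample titles 1 to 4, so a column could be tied to its group and not to its sample. Libraries are named by the column number. Every one of the 8 value columns was used. The file holds 55359 gene identifiers, of which 52083 have a symbol in GENCODE release M21 and carry 99.64% of all counts; features without a symbol took between 0.299% and 0.439% of a library. That release describes GRCm38 and not the build the authors used, so it served for names, transcript lengths and GC content, and no coordinates are given.

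Genes were kept with the filterByExpr rule of edgeR (minimum count 10), which left 15164 features, 44 of them without a symbol and 22 sharing one. Libraries were scaled by TMM (factors 0.989 to 1.01), and a negative binomial model with a quasi-likelihood test (glmQLFit with robust=TRUE, group as the only term) was fitted to all 8 libraries with edgeR 4.0.16 in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method and 0.05 was the threshold. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values use the TMM-scaled totals.

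Before the data were examined, 35 gene lists were fixed, 28 for pathways and processes and 7 for markers of other cell types. Lists with at least 5 tested members (29 lists) were tested by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and by camera with an estimated correlation and fry. Of the 29 lists 16 moved by camera with the preset correlation, 8 higher and 8 lower, and 0 of the 16 held with an estimated correlation (9 of the 29 had an unadjusted p under 0.05 there). Lists with an estimate below 0, such as p53 targets (-0.028), lost their calls too, so correlated members alone do not account for the loss. By fry, which asks only whether members move one way on balance, 22 passed. Camera did not call the osteoblast, matrix protease, clock, apoptosis, histone and fibroblast lists among them. Reactome sets supplied with fgsea 1.28.0, of 15 to 300 tested genes, were tested in the same way after 12357 tested genes were matched to Entrez identifiers. A further 6 lists were written after the data were seen and appear only in the closing observations.

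The rule for naming genes was also fixed then. It took the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 1 CPM, no overlap between the groups and a symbol that is not a predicted-gene name. From each list it took up to 4 members past the threshold with the largest changes, or the 2 with the lowest p if none passed. Some genes that this rule selects are not reported here. Always named were Sost, Dmp1, Phex, Mepe, Fgf23, Pdpn, Gja1, Dkk1, Tnfsf11, Tnfrsf11b, Il6, Ptgs2, Hspa1a, Hspa1b and Cdkn1a.

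The test was tried on simulated data with the real library sizes and the means of the non-irradiated libraries. Of 15194 genes 200 changed, and the members of 5 sets of 20 genes were shifted 1.2-fold besides. All were drawn from genes with a mean of at least 5 CPM, so recovery at lower levels was not tried. Calls of those members did not count as false. Every gene had the same dispersion, the median of the real fit, so the noise was not that of the real data. Counts were drawn in steps of 4 although that dispersion came from the deposited counts, so noise from such steps may be counted in excess. For laser-irradiated against non-irradiated cells it recovered 20.9% of 1.2-fold, 97% of 1.5-fold and 100% of 2-fold changes, and 2.4% of its calls were false. DESeq2 1.42.0 had 10.7% false calls and limma-voom 3%. Camera found 5 of 5 shifted sets of 20 genes and 0 of 20 unshifted ones. The simulated genes varied independently, so this does not show how often camera errs where members vary together. In the real lists the estimated correlation reached 0.634, for ribosomal protein genes.

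Alternatives were DESeq2 size factors, upper-quartile scaling, no filter beyond 1 count, a filter of 1 CPM in 4 libraries, DESeq2's Wald test, limma-voom, rows summed by symbol, libraries thinned to the smallest total, offsets for GC content and transcript length (smooth terms fitted with mgcv 1.9.3 in place of the loess first planned), stricter thresholds, and leaving out each library in turn. Added after the data were seen were counts divided by 4, library totals without scaling, a block by column number, that block with the offsets, and leaving out both libraries numbered 6. Figures were drawn with matplotlib 3.10.9.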

Results

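MLO-Y4 is a mouse cell line with features of osteocytes, the cells embedded in bone matrix that sense load and signal to bone-forming and bone-resorbing cells. The study compared 4 libraries from non-irradiated cells with 4 libraries from cells exposed for 1 min to an Er:YAG laser. This pulsed infrared laser, used in dentistry, emits at 2940 nm, a wavelength that water absorbs strongly. The fluence was 6 J/cm2, a distance of 25 cm separated the emitter from the bottom of the 35-mm dish, and the cells had been seeded 72 h earlier. Total RNA was taken 6 h after irradiation and poly(A) RNA was sequenced. The comparison asks how a single exposure changed gene expression in these cells. Library totals ran from 43786209 to 51734166 counts, and between 19034 and 19508 genes had at least 1 count. Libraries are called C5 to C8 (non-irradiated) and L5 to L8 (irradiated), after the numbers in the deposited table. The labels do not say whether the 4 replicates of a group were separate cultures, so the p-values measure the spread between these samples, which may be only technical. Levels are given as CPM, the usual unit of counts scaled by library total, as mean ± SD with n = 4 per group, and positive log2 fold changes mean higher in irradiated cells.

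Irradiated cells differed from non-irradiated cells in 2270 of 15164 tested genes (15%), of which 1247 were higher and 1023 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Genes of cholesterol synthesis (21 of 24) and of the interferon response (27 of 28) fell in most tested members. Among immediate-early and MAPK feedback genes 17 of 24 rose and 1 fell, among pathway genes of transforming growth factor beta (TGF-beta) and bone morphogenetic protein (BMP) 12 of 22 rose and 1 fell, and the prostaglandin enzyme gene Ptgs2 rose. Most changes were small. The median absolute log2 fold change of the changed genes was 0.25 (1.19-fold), with quartiles of 0.18 and 0.38, and 70 genes changed by at least 1 on the log2 scale, 35 in each direction. Every irradiated library lay above, or every one below, all non-irradiated libraries in 18.5% of tested genes, against 2.86% by chance, and this held for 1969 of the changed genes. The first principal component, with 21.3% of the variance, placed the irradiated libraries between 11.13 and 35.83 and the non-irradiated ones between -25.48 and -15.77. When library totals alone set the scale, 1050 genes were higher and 1345 lower, so that 43.8% of the changed genes were higher against 54.9% with TMM scaling. Among all genes named here, the groups' CPM values overlapped in these changed ones: Cryab, Hspd1, Kif23, Nfat5, Rpl23, Heatr1, Pfkp, Clock and Per1.

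Cholesterol synthesis genes, which the transcription factor SREBP2 controls, formed the most strongly lowered group. Of 24 measured members 21 fell and 3 did not pass the test, with 21 lower when adjusted over the list alone. Insig1 (ENSMUSG00000045294.12), an endoplasmic reticulum protein that holds SREBP back when sterols are plentiful, dropped 2.59-fold, from 77.2 ± 6.12 to 29.8 ± 2.48 CPM (log2 fold change -1.38, SE 0.067, edgeR adjusted p = 8.49e-11). Msmo1, a sterol methyl oxidase, was 2.49-fold lower at 46.9 ± 4.66 against 117 ± 8.9 CPM (adjusted p = 5.24e-09). Hmgcs1, the synthase that makes HMG-CoA, was 2.41-fold lower at 78.7 ± 7.21 against 189.7 ± 14.8 CPM (adjusted p = 1.39e-07), and Cyp51, a sterol demethylase, was 2.09-fold lower (adjusted p = 8.76e-09). The list's median log2 fold change was -0.69, and as a set it was lower than other genes by camera with a preset correlation (adjusted p = 5.33e-23). That call did not hold when camera estimated the correlation from the data (adjusted p = 0.0572).

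Interferon response genes fell by smaller amounts but nearly all together. Of 28 measured members 27 fell and only Rtp4 did not pass the test (log2 fold change -0.016, adjusted p = 0.837), with 27 lower when adjusted over the list alone. Ifit3 (ENSMUSG00000074896.4), an antiviral protein gene, was at 357.8 ± 11.3 CPM in non-irradiated and 209.3 ± 10.3 CPM in irradiated cells (1.71-fold lower, SE of log2 fold change 0.037, adjusted p = 4.43e-11). Mx1, a dynamin-like antiviral GTPase, dropped 1.85-fold from a low level of 8.8 ± 1.31 CPM (adjusted p = 0.00136). Cmpk2 and Zbp1, a mitochondrial nucleotide kinase and a nucleic acid sensor, were 1.35-fold lower in both cases (adjusted p = 5.8e-06 and 8.73e-06). As a set they were lower, with a median log2 fold change of -0.27 (camera adjusted p = 1.21e-20, and adjusted p = 0.0572 with an estimated correlation). Ifit3 has a near-identical copy, and reads from the pair can be split between them in counting.

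**Figure D1:**
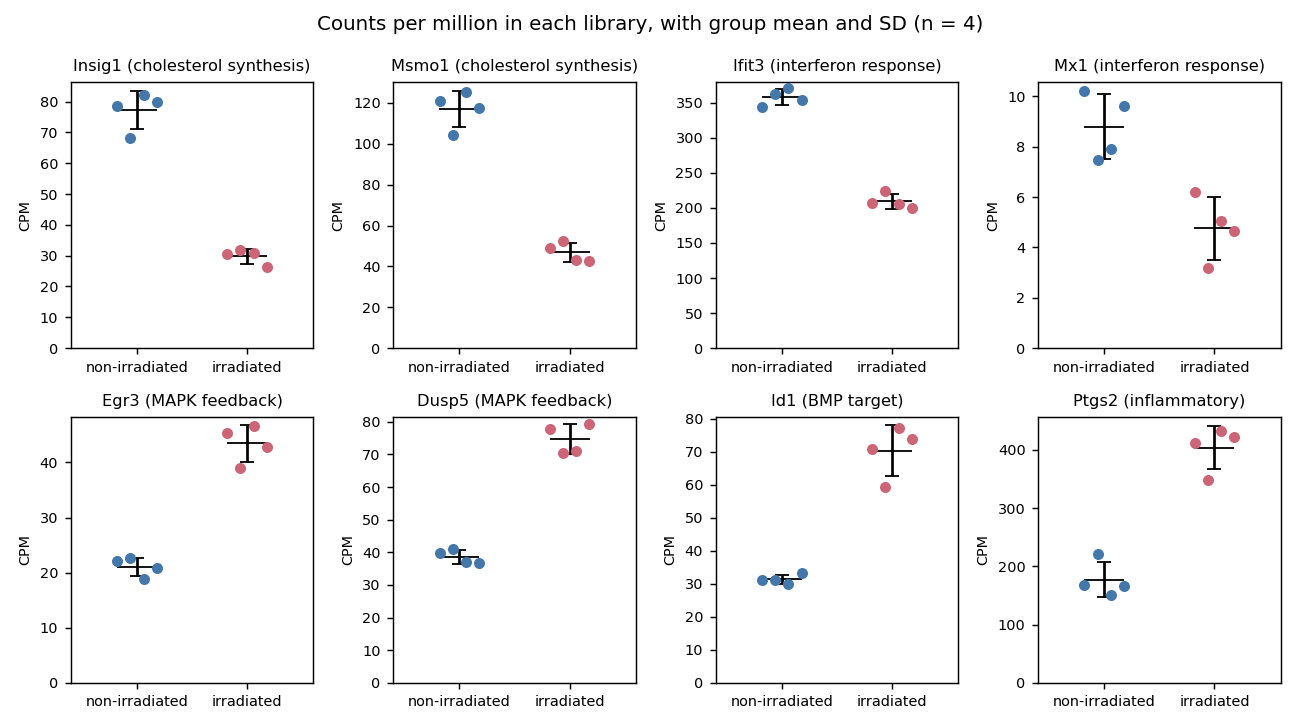
Expression in CPM (linear axes from 0) of 8 genes in each of the 8 libraries; points are libraries, horizontal marks the group mean and bars the SD (n = 4 per group). Insig1, Msmo1, Ifit3 and Mx1 are lower and Egr3, Dusp5, Id1 and Ptgs2 higher in irradiated cells, with no overlap between the groups in any of the 8.

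Immediate-early genes and genes that feed back on mitogen-activated protein kinase (MAPK) signalling were mostly higher 6 h after irradiation. Of 24 members 17 rose, 1 fell and 6 did not pass the test, and 19 were higher and 3 lower when adjusted over the list alone. Egr3 (ENSMUSG00000033730.5), a growth factor-induced transcription factor, rose 2.06-fold from 21.1 ± 1.64 to 43.4 ± 3.39 CPM (log2 fold change 1.04, SE 0.072, adjusted p = 5.24e-09). The dual-specificity phosphatases Dusp5 and Dusp4, which switch MAPKs off, rose 1.93-fold and 1.6-fold (adjusted p = 6.46e-10 and 5.39e-06), and Phlda1 rose 1.61-fold (adjusted p = 2.24e-08). Fos, named after its values were seen, was the member that fell (log2 fold change -0.61, SE 0.121, adjusted p = 0.00153). As a set these genes were higher, with a median of 0.33 on the log2 scale (camera adjusted p = 1.85e-08, and adjusted p = 0.0572 with an estimated correlation). Without C7, or with counts divided by 4, 3 members were lower, and 2 were with DESeq2, upper-quartile scaling, library totals alone, a CPM filter or offsets for GC content and length.

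TGF-beta and BMP pathway genes rose in 12 of 22 members, fell in 1 and did not pass the test in 9, with 13 higher and 1 lower when adjusted over the list alone. Id1 (ENSMUSG00000042745.10), a direct BMP target that blocks differentiation factors, rose 2.24-fold from 31.4 ± 1.39 to 70.3 ± 7.78 CPM (SE of log2 fold change 0.069, adjusted p = 1.35e-09), and its relative Id2 rose 1.76-fold (adjusted p = 1.27e-05). Inhba, which encodes a subunit of activin, rose 1.94-fold from 572.2 ± 94.5 to 1110.0 ± 84.8 CPM (adjusted p = 0.00405). The falling member was Tgfb3, named after its values were seen (log2 fold change -0.29, adjusted p = 0.00213). The list's median log2 fold change was 0.25 (camera adjusted p = 4.93e-06, and adjusted p = 0.177 with an estimated correlation).

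NF-kB and inflammatory genes changed unevenly: 6 of 22 members rose, 1 fell and 15 did not pass the test, with 7 higher and 1 lower when adjusted over the list alone. Ptgs2 (ENSMUSG00000032487.9), the inducible cyclooxygenase that makes prostaglandin precursors, rose 2.28-fold from 176.9 ± 29.9 to 403.8 ± 37.6 CPM (log2 fold change 1.19, SE 0.136, adjusted p = 0.00186). The chemokine gene Cxcl5 rose 1.47-fold (adjusted p = 5.79e-05) and Tnfaip2 rose 1.45-fold (adjusted p = 1.05e-08). Cxcl10, a chemokine that interferons also induce, was the member that fell, by a factor of 1.58 (adjusted p = 3.65e-05). Il6 stood at 5.24 ± 0.803 CPM in non-irradiated and 5.3 ± 0.792 CPM in irradiated cells (log2 fold change 0.019, SE 0.159, adjusted p = 0.96). Members had a median log2 fold change of 0.046 and the set was higher by camera (adjusted p = 0.0185, and adjusted p = 0.278 with an estimated correlation). The median was 0.024 with library totals alone, 0.09 without C6 and 0.096 without both libraries numbered 6. Without L5 the set call ended (adjusted p = 0.071) and 2 members were lower.

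Targets of YAP and SRF, transcription factors that respond to cell shape and tension, rose in 11 of 23 members, fell in 2 and did not pass the test in 10; adjusted over the list alone, 12 were higher and 3 lower. Ccn1 and Ccn2, secreted matrix-associated proteins, rose 1.64-fold (133.8 ± 4.54 to 219.5 ± 26.5 CPM, adjusted p = 0.000406) and 1.6-fold (adjusted p = 1.2e-05), and Ankrd1 rose 1.62-fold (adjusted p = 2.17e-05). The members that fell were F3, the gene of tissue factor (log2 fold change -0.76, SE 0.247, adjusted p = 0.0429), and Axl, named after its values were seen (log2 fold change -0.13, adjusted p = 0.00208). Camera called the set higher at a median log2 fold change of 0.14 (camera adjusted p = 0.000129, and adjusted p = 0.128 with an estimated correlation). F3 lost its call without any library other than L5 (adjusted p up to 0.13, without L7), without both libraries numbered 6 (0.158), with offsets for GC content and length (0.0527), in thinned libraries (0.0584) and with a filter of 1 count (0.0549), and 1 member was lower without C5, C7, C8, L6, L7 or L8.

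Osmotic stress genes, targets of NFAT5, rose in 6 of 13 members, fell in 1 and did not pass the test in 6, and 7 were higher and 2 lower when adjusted over the list alone. Slc6a12, a betaine transporter, showed one of the largest rises in the data at 3.31-fold, from 0.818 ± 0.527 to 2.72 ± 0.574 CPM (log2 fold change 1.73, SE 0.378, adjusted p = 0.00453). The water channel gene Aqp1 rose 1.43-fold to 153.3 ± 5.46 CPM (adjusted p = 3.82e-08), the kinase gene Sgk1 rose 1.31-fold (adjusted p = 4.24e-07) and Nfat5 itself rose 1.19-fold (adjusted p = 0.00185). This set too was higher, with a median log2 fold change of 0.14 (camera adjusted p = 0.0196, and adjusted p = 0.128 with an estimated correlation). With offsets for GC content and length the median was 0.08. The lower member, Hspa4l (log2 fold change -0.19, adjusted p = 0.0448), lost its call without any library other than C8 (adjusted p up to 0.136, without C7), without both libraries numbered 6 (0.107), with a filter of 1 count (0.0567) and with limma-voom (0.0559), and 2 members were lower with library totals alone.

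Matrix protease and remodelling genes went both ways, with 7 of 21 members higher, 5 lower and 9 not past the test, the same counts when adjusted over the list alone. The protease genes Mmp13 (1.63-fold, adjusted p = 0.0126), Mmp11 (1.49-fold, adjusted p = 4.9e-06) and Plau (1.49-fold, adjusted p = 0.00444) rose. The members that fell were Ctsk (log2 fold change -0.2), Timp2 (-0.19), Adamts5 (-0.32), Lox (-0.13) and Plat (-0.14), the last 4 named after their values were seen. The set did not differ from other genes by camera (adjusted p = 0.251), though fry called it (adjusted p = 0.0177). Mmp13 lost its call without C7, L7 or L8 (adjusted p up to 0.0527, without L7), and Ctsk without C7 or L6 (adjusted p up to 0.0745, without C7), without both libraries numbered 6 (0.131) and with offsets for GC content and length (0.0639).

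Of 12 measured osteocyte genes 6 rose, 2 fell and 4 did not pass the test, the same counts when adjusted over the list alone. Gja1 (ENSMUSG00000050953.11), the connexin that joins neighbouring osteocytes, rose 1.27-fold from 250.1 ± 5.17 to 318.4 ± 9.91 CPM (log2 fold change 0.35, SE 0.032, adjusted p = 1.84e-07). Pdpn, the podoplanin gene of early osteocyte dendrites, rose 1.25-fold from 486.8 ± 12.6 to 608.4 ± 23.2 CPM (adjusted p = 4.88e-07). Mmp14, a membrane-bound collagenase, rose 1.21-fold (adjusted p = 9.04e-06) and Mmp13 1.63-fold (adjusted p = 0.0126). Ank and Capg, named after their values were seen, fell (log2 fold changes -0.2 and -0.16, adjusted p = 0.000927 and 0.000324). Phex, a protease gene that controls mineralization, gave 15 ± 1.86 against 16 ± 0.187 CPM (adjusted p = 0.559), and Tnfsf11, which encodes RANKL, gave 72.6 ± 13.4 against 69 ± 2.41 CPM (log2 fold change -0.072, SE 0.12, adjusted p = 0.78). Over the 12 members the median log2 fold change was 0.13 (camera adjusted p = 0.0196, and adjusted p = 0.315 with an estimated correlation). Without C7 the set call ended (adjusted p = 0.0541), and Mmp13 lost its call without C7, L7 or L8 (adjusted p up to 0.0527, without L7).

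Markers of mature osteocytes were at or near the limit of detection. Sost, Mepe, Fgf23 and Dkk1 had 0 counts in each of the 8 libraries, which allows up to 0.0685 CPM (3 counts of the smallest library) and up to 0.274 CPM if a fragment adds 4 counts. Dmp1 had 21 counts over the non-irradiated libraries (0, 0, 12 and 9) and 61 over the irradiated ones (3, 10, 29 and 19), and Tnfrsf11b, the gene of osteoprotegerin, had 8 and 14. These genes were below the expression filter and their difference was not tested. Limits of this kind cover counting error only.

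Osteoblast and bone matrix genes were not called as a set by camera (adjusted p = 0.321) but were by fry (adjusted p = 0.0353). Of 16 members 3 were higher, 2 lower and 11 not past the test, or 5 higher and 2 lower when adjusted over the list alone. With offsets for GC content and length 5 members were higher. Alpl, the phosphatase of mineralizing cells, rose 1.23-fold from 33.2 ± 2.86 to 40.8 ± 2.24 CPM (adjusted p = 0.00371). Col1a2, a chain of type I collagen, rose 1.19-fold (adjusted p = 0.00151) and the osteoblast transcription factor gene Runx2 1.18-fold (adjusted p = 0.005). Atf4 (log2 fold change -0.16, adjusted p = 0.00094) and Lox, named after its values were seen (-0.13, adjusted p = 0.000675), fell.

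Heat shock (HSF1) genes did not move as a set 6 h after irradiation (camera adjusted p = 0.76). The inducible chaperone genes Hspa1a and Hspa1b gave log2 fold changes of 0.14 (SE 0.151, adjusted p = 0.619) and 0.12 (SE 0.089, adjusted p = 0.403), with 5.52 ± 0.183 against 6.08 ± 1.14 CPM and 18.2 ± 2.32 against 19.9 ± 1.12 CPM. They are near-identical and can share reads. Of 20 members 3 rose, 2 fell and 15 did not pass the test, the same counts when adjusted over the list alone, and the list's median and mean log2 fold change (0.003 and -0.013) differ in sign, the test leaning higher. Hsph1 rose 1.22-fold (adjusted p = 2.54e-05), Hspd1 1.08-fold (adjusted p = 0.0221) and Hsp90aa1, named after its values were seen, 1.07-fold (adjusted p = 0.0194). Cryab (log2 fold change -0.48, adjusted p = 0.023) and Hspa4l (-0.19, adjusted p = 0.0448) fell. Hsph1 apart, these calls were fragile. Cryab was lost without C5, C7, C8, L6, L7 or L8 (adjusted p up to 0.0826, without L8), Hspa4l as given above, Hspd1 without C5, C7, L5 or L8 (up to 0.0829, without C5) or with library totals alone (0.065) and Hsp90aa1 without C5, C8, L5, L7 or L8 (up to 0.0639, without L7) or with library totals alone (0.0687). Only 1 member was higher without C5, L5 or L8 or with library totals alone, and 0 or 1 lower without any one library.

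Endoplasmic reticulum chaperone genes, part of the unfolded protein response, rose in 6 of 21 members and 15 did not pass the test, with 6 higher when adjusted over the list alone. Hspa5, the main chaperone gene of this compartment, rose 1.16-fold from 1578 ± 34.9 to 1832 ± 32.3 CPM (adjusted p = 5.23e-06), Herpud1 rose 1.25-fold (adjusted p = 8.93e-05), and Hyou1 and Creld2 each 1.12-fold (adjusted p = 0.000556 and 0.0148). Chaperone genes as a set were higher at a median of 0.051 (camera adjusted p = 0.00264, and adjusted p = 0.0572 with an estimated correlation). The median was 0.028 with library totals alone, and Creld2 lost its call without C7 (adjusted p = 0.053).

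ATF4 and amino acid response genes had 6 of 26 members lower, 1 higher and 19 not past the test, or 8 lower and 1 higher when adjusted over the list alone. Chac1 and Nupr1, stress-induced ATF4 targets, dropped 1.27-fold and 1.26-fold (adjusted p = 0.00943 and 0.000324), Pycr1, a proline synthesis enzyme, 1.24-fold (adjusted p = 0.0246) and Ddit3, the CHOP transcription factor gene, 1.16-fold (adjusted p = 0.0307). Cth, named after its values were seen, rose (log2 fold change 0.19, adjusted p = 0.00145). Together these genes were lower at a median log2 fold change of -0.11 (camera adjusted p = 0.00442, and adjusted p = 0.128 with an estimated correlation). Without C5 or L8 3 members were lower, and with offsets for GC content and length 2 were higher. Pycr1 lost its call without C5, C7, L5, L6 or L8 (adjusted p up to 0.0817, without L5), and Ddit3 without C5, C6, C8, L5, L7 or L8 (up to 0.101, without L8) and with offsets for GC content and length (0.108). Without both libraries numbered 6 Pycr1 (0.0627) and Ddit3 (0.055) lost theirs too.

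NRF2 oxidative stress genes fell in 12 of 22 members, rose in 1 and did not pass the test in 9, or 14 lower and 2 higher when adjusted over the list alone. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, dropped 1.53-fold from 125.1 ± 2.16 to 81.5 ± 5.83 CPM (log2 fold change -0.62, SE 0.046, adjusted p = 1.39e-08). Gstm1, a glutathione transferase, was 1.21-fold lower (adjusted p = 0.00472) and Tkt, an enzyme of the pentose phosphate pathway, 1.18-fold lower (adjusted p = 8.65e-05). Srxn1, a reductase of oxidized peroxiredoxins, was the member that rose, 1.19-fold (adjusted p = 1.17e-05). By camera the set was lower, with a median of -0.14 on the log2 scale (camera adjusted p = 0.00155, and adjusted p = 0.218 with an estimated correlation). Without L7 7 members were lower, and without C6, or both libraries numbered 6, 2 were higher.

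Targets of p53 were lower in 5 of 20 members, higher in 1 and not past the test in 14, the same counts when adjusted over the list alone. Trp53inp1 dropped 1.6-fold from 93 ± 5.83 to 58.2 ± 4.02 CPM (adjusted p = 4.09e-08), and Eda2r and Zmat3 were 1.2-fold and 1.17-fold lower (adjusted p = 0.019 and 0.000101). Mdm2 and Ccng1, named after their values were seen, also fell (log2 fold changes -0.16 and -0.21), and Polk, a DNA polymerase, rose 1.19-fold (adjusted p = 0.00147). Cdkn1a, the cell cycle inhibitor p21, stood at 397.7 ± 15.3 and 381.9 ± 12.9 CPM (log2 fold change -0.058, SE 0.034, adjusted p = 0.279). Lower as a set by camera, p53 targets had a median log2 fold change of -0.099 (camera adjusted p = 0.00264, and adjusted p = 0.0572 with an estimated correlation). Without C6 the median was -0.15. Eda2r lost its call without C5 or L8 (adjusted p up to 0.0964, without C5) and without both libraries numbered 6 (0.0699).

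Hypoxia and glycolysis genes split, with 5 of 25 members higher, 4 lower and 16 not past the test, or 6 higher and 5 lower when adjusted over the list alone. Vegfa, the vascular growth factor, rose 1.37-fold from 150.1 ± 10.9 to 205.3 ± 6.78 CPM (adjusted p = 7.83e-07) and the glucose transporter Slc2a1 1.3-fold (adjusted p = 3.23e-06). Ndrg1 and Bnip3, both induced by low oxygen, fell (log2 fold changes -0.41 and -0.4, adjusted p = 0.000288 and 0.000274). Named after their values were seen, Hk2 (log2 fold change 0.38), Ero1l (0.14) and Pfkp (0.15, adjusted p = 0.0477) also rose, and Kdm3a (-0.29) and Tpi1 (-0.11) fell. The set did not move (camera adjusted p = 0.583), and its median and mean log2 fold change (-0.008 and 0.023) differ in sign, the test leaning higher. Without C5 3 members were higher, and Ero1l lost its call (adjusted p = 0.0542), as did Pfkp without C5, C7, C8, L5, L7 or L8 (up to 0.164, without C8) with offsets for GC content and length (0.294), with library totals alone (0.0853), with upper-quartile scaling (0.0601) and with limma-voom (0.0622).

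G2 and mitosis genes fell in 10 of 28 members and 18 did not pass the test, with 14 lower when adjusted over the list alone. Nusap1, a spindle protein, was 1.24-fold lower at 44.4 ± 0.826 against 55.2 ± 3.26 CPM (adjusted p = 0.000288), Cdc20 and Cenpf were 1.14-fold and 1.13-fold lower (adjusted p = 0.000523 and 0.00246), and Kif23 was 1.13-fold lower (adjusted p = 0.0295). Mitosis genes were lower as a set at a median of -0.1 (camera adjusted p = 2.86e-06, and adjusted p = 0.0572 with an estimated correlation). S-phase and DNA replication genes did not move as a set (camera adjusted p = 0.41), with 2 of 28 members higher, 1 lower and 25 not past the test, or 1 higher and 1 lower when adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, rose 1.37-fold from 701.5 ± 10 to 959.9 ± 41.9 CPM (adjusted p = 4.2e-09), Ccne1 rose 1.1-fold (adjusted p = 0.049) and the helicase gene Mcm6 fell (log2 fold change -0.14, adjusted p = 0.00401). Kif23 lost its call without C5, C7, C8, L7 or L8 (adjusted p up to 0.13, without L7). Ccne1 lost it without any library other than C6 (up to 0.14, without C7), with library totals alone (0.0979), with upper-quartile scaling (0.065) and with a filter of 1 count (0.0648), and 2 S-phase members were lower with library totals alone or offsets for GC content and length, and 1 was higher without C5, C7, C8, L5, L6 or L8.

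Of 17 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 2 rose and 15 did not pass the test, with 2 higher when adjusted over the list alone. The linker histone genes Hist1h1c and Hist1h1d rose 1.68-fold (138.7 ± 10.3 to 233.1 ± 4.46 CPM, adjusted p = 6.46e-10) and 1.7-fold (adjusted p = 0.00429). Camera did not call the set (adjusted p = 0.129), but fry did (adjusted p = 0.00263). The list's median and mean log2 fold change (-0.033 and 0.068) differ in sign, camera leaning higher. Histone genes are near-identical and can share reads.

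Of 32 cytosolic ribosomal protein genes 10 were lower and 22 not past the test, with 16 lower when adjusted over the list alone. Rps14 dropped 1.1-fold from 398.8 ± 13.4 to 363.1 ± 7.15 CPM (adjusted p = 0.00463), and Rpl10, Rpl23 and Rpl4 were 1.09-fold, 1.09-fold and 1.08-fold lower (adjusted p = 0.0134, 0.0371 and 0.0105). The median log2 fold change was -0.083 (camera adjusted p = 1.73e-05, and adjusted p = 0.396 with an estimated correlation). These are short transcripts. Relative to the mean of all 8 libraries, expression changed by 0.0221 ± 0.0144 log2 units per doubling of length in irradiated libraries. In non-irradiated ones the slope was -0.0221 ± 0.034. Slopes taken about that mean must mirror each other, so only their difference has meaning (0.0443, n = 4 each, exact two-sided permutation p = 0.0857). With offsets for GC content and length the list's median was -0.042, and camera with the preset correlation still called it (adjusted p = 0.00564). With these offsets 4 members were lower, and Rpl10 and Rpl23 lost their calls (adjusted p = 0.0815 and 0.13). The count also hung on single libraries, with 4 lower without C5, L5 or L8, 3 without C7 or L7, 2 without C8, 22 without C6 and 23 without both libraries numbered 6, and on the method, with 16 by library totals alone and 6 by limma-voom. Rpl10 lost its call without C8 or L5 (adjusted p up to 0.062, without L5), Rpl23 without C5, C7, C8, L7 or L8 (up to 0.158, without L7) or with limma-voom (0.0615) and Rpl4 without L7 (0.0536).

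Of 24 ribosome biogenesis genes 7 were higher and 17 not past the test, with 10 higher when adjusted over the list alone. Nop56, a nucleolar protein, rose 1.26-fold from 161.6 ± 9.41 to 202.9 ± 9.36 CPM (adjusted p = 2.03e-05), and Rrp1b, Heatr1 and Gnl3 rose 1.23-fold, 1.17-fold and 1.15-fold (adjusted p = 0.0256, 0.00927 and 0.00831). The median log2 fold change was 0.098 (camera adjusted p = 0.00167, and adjusted p = 0.39 with an estimated correlation). Without C6, or both libraries numbered 6, 11 members were higher and without C7, C8, L7 or L8 there were 4, and Rrp1b lost its call without C7, C8, L7 or L8 (adjusted p up to 0.104, without L7) and with limma-voom (0.0516).

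Lysosome and autophagy genes fell in 7 of 25 members and 18 did not pass the test, with 10 lower when adjusted over the list alone. Sqstm1, the p62 receptor that carries cargo to autophagosomes, fell from 503.6 ± 6.4 to 380.1 ± 8.41 CPM (adjusted p = 5.24e-09), and Atg7, Atg12 and Wipi1, parts of the autophagosome machinery, were 1.23-fold, 1.2-fold and 1.18-fold lower (adjusted p = 0.0011, 0.0115 and 0.00245). The median log2 fold change was -0.084 (camera adjusted p = 9.85e-05, and adjusted p = 0.153 with an estimated correlation). Without C8 the median was -0.055. Atg12 lost its call without C8 (adjusted p = 0.0563) and without both libraries numbered 6 (0.0506). Of 23 apoptosis genes 2 fell and 21 did not pass the test, the same when adjusted over the list alone. Camera did not call the set (adjusted p = 0.103), but fry did (adjusted p = 0.00576). The fall in Bmf, which promotes cell death (log2 fold change -0.75, adjusted p = 0.0232), was lost without C7, C8 or L5 (up to 0.0925, without C7). No apoptosis member stayed lower without C7, C8 or L5, and 1 did without L7.

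Genes of mitochondrial respiration did not pass the planned edgeR test of all libraries. Among 24 nuclear oxidative phosphorylation genes edgeR called 0, with 1 lower at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Ndufv1 had the lowest p (log2 fold change -0.13, adjusted p = 0.0892). Among 13 mitochondrially encoded genes edgeR called 0, with 2 higher at an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 1, and mt-Co1 and mt-Nd1 had log2 fold changes of 0.057 and 0.074 (adjusted p = 0.0854 and 0.106). Counts adjusted over the list alone were 0 for both lists, and neither set moved (camera adjusted p = 0.179 and 0.264, and 0.599 and 0.668 with an estimated correlation). The estimated correlation was used only with all libraries and no offsets. Without C6, Ndufv1 was lower (edgeR adjusted p = 0.00678) and so was the nuclear set (camera adjusted p = 0.0316), and with offsets for GC content and length the mitochondrially encoded set was higher (camera adjusted p = 0.00548), as were mt-Co1 (log2 fold change 0.1, adjusted p = 7.17e-05) and mt-Nd1 (0.13, adjusted p = 0.000314). By limma-voom mt-Co1 was higher too (adjusted p = 0.0238), and with library totals alone Ndufv1 was lower (0.047).

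Of the signalling lists that did not move as sets, Wnt genes had 2 of 12 members higher, 1 lower and 9 not past the test (camera adjusted p = 0.529), or 3 higher and 2 lower when adjusted over the list alone. Tcf7, a transcription factor of the pathway, rose 1.68-fold from 20.5 ± 2.89 to 34.4 ± 3.93 CPM (adjusted p = 7.27e-05), Ccnd1, the cyclin D1 gene, rose 1.22-fold (adjusted p = 1.28e-06) and the receptor gene Fzd2 dropped 1.29-fold (adjusted p = 0.000269). With library totals alone or offsets for GC content and length 2 Wnt members were lower. Notch genes had 2 of 14 members higher, 2 lower and 10 not past the test, the same counts adjusted over the list alone (camera adjusted p = 0.243). Hes1 and Notch2 rose 1.43-fold and 1.2-fold (adjusted p = 4.87e-05 and 0.00034), while Notch1 and the ligand gene Jag1 dropped 1.18-fold and 1.26-fold (adjusted p = 0.00769 and 0.0233). Jag1 lost its call without C5, C7, C8, L7 or L8 (adjusted p up to 0.078, without L8), which left 1 Notch member lower.

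Circadian clock genes moved in both directions, with 4 of 17 members higher, 4 lower and 9 not past the test, the same counts when adjusted over the list alone. Camera did not call the set (adjusted p = 0.103), but fry did (adjusted p = 0.00018). Arntl, the gene of the clock activator BMAL1, rose 1.46-fold from 15.5 ± 1.68 to 22.5 ± 1.4 CPM (adjusted p = 0.00016). The output genes Dbp and Tef dropped 1.68-fold and 1.23-fold (adjusted p = 0.00145 and 0.000152) and Per3 dropped 1.65-fold (adjusted p = 3.98e-05). Named after their values were seen, Nr1d2 fell (log2 fold change -0.24, adjusted p = 0.00295) and Per1 (0.26, adjusted p = 0.0122), Clock (0.18, adjusted p = 0.0189) and Bhlhe40 (0.15, adjusted p = 0.0171) rose. Without C5, C8 or L8 2 members were higher: Clock lost its call without C5, C7, C8 or L5 (up to 0.0724, without C7) and with offsets for GC content and length (log2 fold change 0.09, adjusted p = 0.0585), Per1 without C8 or L8 (up to 0.0631, without L8) and Bhlhe40 without C5, L6 or L8 (up to 0.0716, without C5). Without L7 the set was lower (camera adjusted p = 0.0358).

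**Figure D2:**
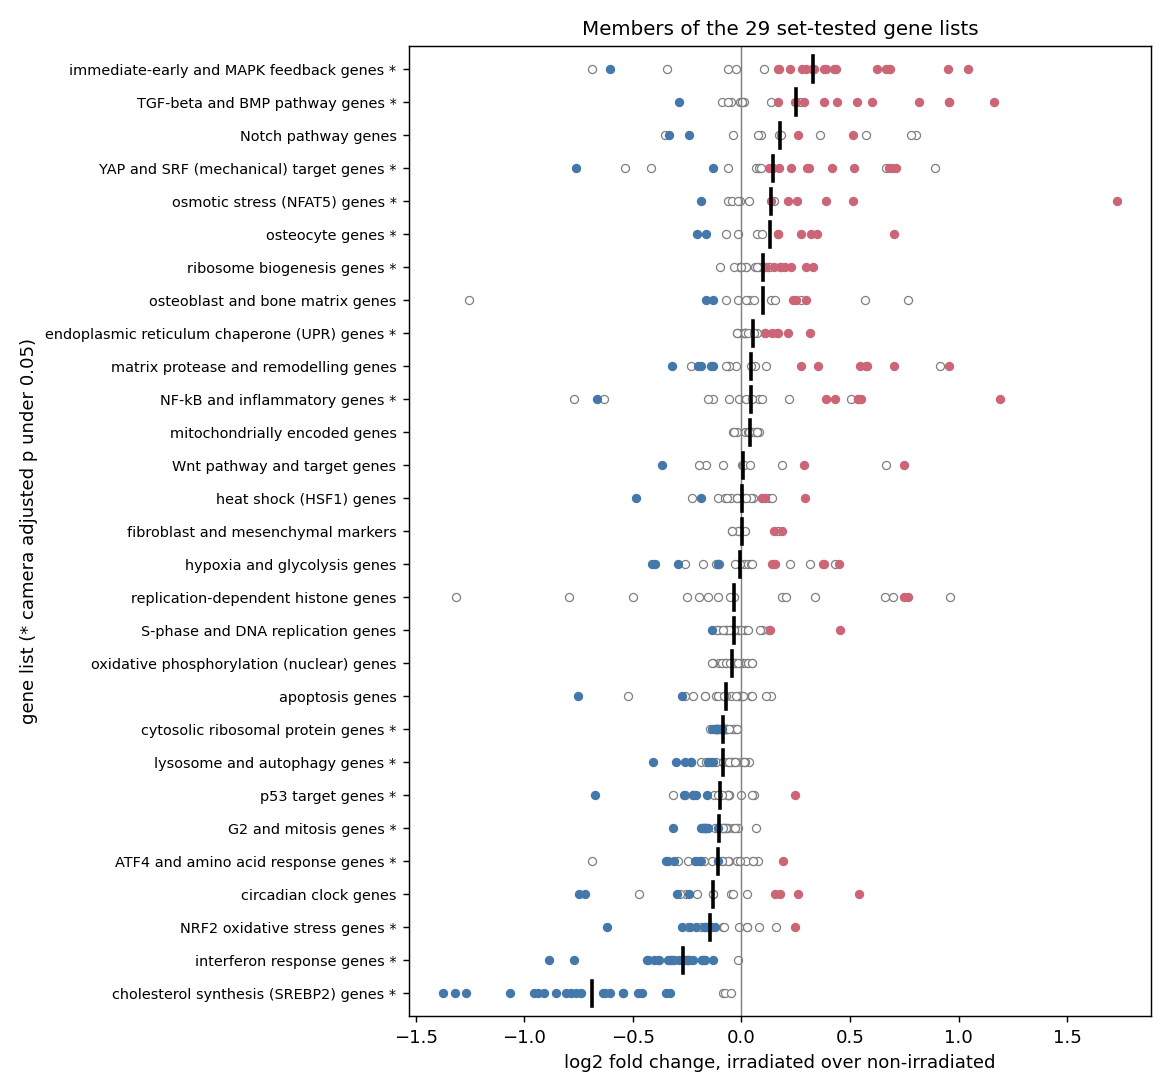
Log2 fold changes (irradiated over non-irradiated) of the members of the 29 gene lists with at least 5 tested genes; filled points passed an edgeR adjusted p of 0.05 (blue lower, red higher), open points did not, black bars mark list medians and asterisks sets moved by camera with a preset correlation. Cholesterol synthesis and interferon response genes lie almost entirely below 0, with medians of -0.69 and -0.27, and immediate-early genes mostly above, with a median of 0.33.

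Markers of other cell types were mostly absent. Of 15 macrophage and osteoclast markers 3 could be tested, and Ptprc, Adgre1, Itgam, C1qa and Tyrobp had 0 counts in each library. Csf1r, the receptor for macrophage colony-stimulating factor, rose 1.85-fold from 14.2 ± 1.17 to 26.2 ± 1.2 CPM (adjusted p = 1.06e-07), and Ctsk dropped 1.15-fold (adjusted p = 0.0188; lost without C7, at 0.0745, L6, at 0.0739, or both libraries numbered 6, at 0.131, and with offsets for GC content and length, at 0.0639), so that the median and mean log2 fold change of the 3 (-0.2 and 0.12) differ in sign. Sox9, a chondrocyte transcription factor gene, rose 1.55-fold from 138 ± 1.72 to 214.2 ± 7.12 CPM (adjusted p = 2.29e-10), as 1 of 4 tested chondrocyte markers, while Acan had 0 counts. Pparg, 1 of 4 tested adipocyte markers, rose 1.18-fold (adjusted p = 0.0251; lost without C5, C7, C8, L7 or L8, at most 0.0822 without L8), and Adipoq had 0 counts. Krt19 was the only epithelial marker of 10 that could be tested and rose 2.46-fold, with Epcam, Krt8 and Cdh1 at 0 counts. Fibroblast and mesenchymal markers were mostly abundant, but Thy1 and Lum had at most 20 and 17 counts in a library and were not tested. Of 8 tested markers 2 were higher, Pdgfra 1.14-fold (adjusted p = 0.000823) and Pdgfrb 1.11-fold (adjusted p = 0.00328). Camera did not call the set (adjusted p = 0.341), but fry did (adjusted p = 0.0084). Of 3 skeletal muscle and 2 endothelial markers edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Mylpf and Actn3 had log2 fold changes of 0.28 and 0.25 (adjusted p = 0.587 and 0.789), and Egfl7 and Vwf of -0.25 and 0.46 (adjusted p = 0.282 and 0.694). Each of these 7 lists gave the same counts when adjusted over the list alone.

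The largest rises were in genes of low expression. Cpm (ENSMUSG00000020183.12), which encodes carboxypeptidase M, rose 4.23-fold from 2.62 ± 0.899 to 11.1 ± 1.23 CPM (log2 fold change 2.08, SE 0.202, adjusted p = 1.84e-06), and was followed by Slc6a12. The keratin genes Krt13 and Krt19 rose 2.61-fold and 2.46-fold (from 8.04 ± 0.877 and 10.2 ± 0.952 CPM in non-irradiated cells, adjusted p = 8.62e-09 and 2.82e-09). Foxn1 and Trp63, transcription factors of epithelia, rose 2.77-fold and 2.39-fold (adjusted p = 0.00771 and 0.00677). The others were Rem2 (3.09-fold), Cyp26b1, a retinoic acid-degrading enzyme (2.81-fold), Palm2 (2.46-fold), Tmem179 (2.45-fold), Adora2a, an adenosine receptor (2.45-fold), and Ramp3, a partner of calcitonin-family receptors (2.43-fold). Their adjusted p ran from 4.5e-07 for Tmem179 to 0.00518 for Adora2a.

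The largest falls, besides Insig1, Msmo1 and Hmgcs1, were also in weakly expressed genes. Syna (ENSMUSG00000085957.5), which encodes syncytin-A, dropped 2.63-fold from 2.96 ± 0.26 to 1.13 ± 0.197 CPM (log2 fold change -1.39, SE 0.228, adjusted p = 0.000223). H2-K2, a class I histocompatibility gene with close paralogs, dropped 2.6-fold (adjusted p = 0.00682) and Mill2, a distant relative of that family, 2.12-fold (adjusted p = 0.0046). Prrt2 (2.5-fold), Ypel2 (2.33-fold) and the cartilage collagen gene Col11a2 (2.12-fold) were lower with adjusted p = 0.00801, 0.000866 and 0.000538. Sema4g (2.27-fold), Eln, the elastin gene (2.16-fold), and Abca4 (2.15-fold) were lower with adjusted p = 0.0371, 0.0236 and 0.0275. Sema4g lost its call without C5, C7, C8, L5 or L8 (adjusted p up to 0.101, without L8), Eln without C5, C7, L6 or L7 (up to 0.13, without C7) or with limma-voom (0.065) and Abca4 without C5, C7, C8, L5, L6 or L7 (up to 0.0877, without C5).

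Across 647 Reactome sets, camera moved 142, of which 39 were higher and 103 lower. The strongest were lower sets of cholesterol biosynthesis (23 genes, 17 lower, median log2 fold change -0.61, adjusted p = 1.3e-13) and of gene expression activated by SREBP (23 genes, 15 lower, adjusted p = 1.22e-08). Interferon gamma signaling was lower too (64 genes, 29 lower and 8 higher, adjusted p = 0.000126), as was the translation elongation set, which holds many ribosomal protein genes (87 genes, median log2 fold change -0.078, adjusted p = 8.18e-05). Among the higher sets were cell and extracellular matrix interactions (18 genes, 12 higher, adjusted p = 0.000414) and BMP signaling (19 genes, 7 higher, adjusted p = 0.00455). With an estimated correlation 0 sets passed (smallest adjusted p = 0.35), and 76 had an unadjusted p under 0.05. With offsets for GC content and length 44 sets moved.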

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

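The tests of mixed libraries and of the number of genes over other splits were chosen only after the result was seen. Of 376 groups of 4 values tested, 17 (4.5%) held a library far from the other 3, about the 5% that chance gives. Library 6 of either group accounts for 10 of them. In L6, Gstm1 (53.95 CPM), Ndrg1 (37.87), Tef (55.15) and Scd2 (628.4) were high and Ccnd1 (422.6) and Hsp90aa1 (1042 CPM) low. In C6, Srebf2 (237.2 CPM) and Fads2 (84.8) were low and Areg (22.71) and Csf1 (2368 CPM) high. The other 7 were Herpud1 (66.02 CPM, high in L8), Hyou1 (298.4, high in L7), Rps14 (418.7, high in C7), Vwf (0.0627, low in L5), Phex (15.73, low in L5), Timp2 (1011, low in L5) and Cth (132.6 CPM, low in L8).

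Each of the 10 values from libraries numbered 6 lay towards the other group. Over genes called without the library in question, C6 lay 0.23 of the way to the irradiated mean (722 genes) and L6 lay 0.23 of the way to the non-irradiated mean (664 genes), against -0.06 to 0.02 in the other 6 libraries. Mixing of RNA or reads between them would move all gene groups by a like share, and as the whole cause the tables argue against it. In C6 the median share was 0.24 for cholesterol synthesis and 0.28 for TGF-beta genes. It was 0.09 for immediate-early and -0.01 for interferon response genes, a range of 0.29 over 4 lists. In L6 the share was 0.12 for cholesterol synthesis, 0.14 for interferon response, 0.25 for immediate-early and 0.38 for TGF-beta genes, a range of 0.26. All 4 lists in L6 thus lay towards the other group, though by unlike shares. The other 6 libraries had ranges of 0.128 ± 0.029 (SD), at most 0.18. Partial mixing beside ordinary variation, and a difference in the handling or response of these dishes, stay open and untested.

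Other groupings of the 8 libraries do not give the counts reported. Only the real one of the 35 splits called 2270 genes (highest other 2), 16 lists (highest other 13) and 142 Reactome sets (highest other 137), which is 1 of 35 in each case. For each count 1 of 35 is the smallest share these splits allow, so chance is not excluded. If the libraries of a group came from a single culture, a chance difference between cultures would also set the real split apart. The margin was wide for genes, but the other splits mix the groups. Mixing adds the difference between the groups to the spread within them, which leaves few gene calls. For lists and Reactome sets the margin was small, with 137, 126 and 124 sets in the next splits. The split with 137 sets and 13 lists parts the libraries with the 4 lowest length slopes (C5, C7, C8 and L6) from the rest. It called 0 genes with edgeR, and with offsets for GC content and length it gave 20 sets against 44 in the real split. Its lists still numbered 13 with these offsets, against 17 in the real split.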

How the results depend on the processing

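Counts divided by 4, library totals without scaling, the block by column number, that block with the offsets and the removal of both libraries numbered 6 were chosen after the data were seen. Over 22 alternatives (20 for Actn3 and Vwf), 147 of 187 genes chosen for naming and 23 of 29 gene lists kept their side of the threshold. Signs changed only in results that edgeR or camera had not called: Tnfsf11 (log2 fold change -0.15 to 0.07), Il6 (-0.06 to 0.11) and the medians of the heat shock, hypoxia, Wnt, matrix protease, histone and fibroblast lists. Stricter thresholds gave 1283 genes changed in laser-irradiated against non-irradiated cells (776 genes higher in laser-irradiated cells, 507 genes lower in laser-irradiated cells) at an adjusted p under 0.01 and 70 (35 higher, 35 lower) with an absolute log2 fold change of at least 1. Without single libraries, 1672 to 2673 genes changed, 976 to 1501 higher and 696 to 1172 lower, with 15 to 17 lists and 121 to 157 Reactome sets moved. Without both libraries numbered 6, 2733 genes changed, 2017 of them among the 2270. Reactome sets fell from 142 to 44 with offsets for GC content and length and to 6 with these offsets and the replicate block (the cause was not tested). With an estimated correlation 0 Reactome sets and 0 of the 29 lists passed. No paired analysis by the title numbers was possible because the columns carry other numbers. A replicate block by column number gave 1757 changed genes, and same-numbered libraries did not vary together (correlations 0.02, -0.14, -0.15 and -0.01, with 0 of 8 libraries closest to their own number), so the numbers, which rest on column names alone, were not taken to pair the samples. That check finds only shifts in the same direction. It cannot exclude shared handling of same-numbered dishes, since C6 and L6 each lay towards the other group. Osteocyte genes (camera adjusted p = 0.0546) and osmotic stress genes (0.0539) lost their calls with the offsets and that block. With the block alone Inhba lost its call (0.0571), as did Abca4, Hspa4l, Hspd1, Ccne1, Kif23, Pycr1, F3, Rpl23, Rrp1b, Pparg, Hsp90aa1, Pfkp and Scd1 (adjusted p from 0.0543 for Pycr1 to 0.104 for Rrp1b). With the offsets and the block Plau (0.0801), Rps14 (0.0744), Rpl4 (0.0753), Tpi1 (0.0563) and Per1 (0.0665) lost theirs. Lower ribosomal protein genes numbered 3 with the block and 0 with the block and offsets, against 10, higher ribosome biogenesis genes 4 with the block, against 7, and higher clock genes 2 with the block and offsets, against 4. The self-test, with its simulated noise and no weakly expressed genes among those changed, recovered 20.9% of 1.2-fold changes. At this depth and number of libraries many changes of that size may thus go uncalled.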

Other observations

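The 6 gene lists and the genes named in this part were chosen after the data were seen; the tests on FOXO and LXR targets were written down before their results were. Fatty acid synthesis genes fell along with those of cholesterol synthesis: 13 of 16 were lower and 1 higher, with a median log2 fold change of -0.29 (camera adjusted p = 6.94e-11 over the 6 lists, and adjusted p = 0.0451 with an estimated correlation). Scd2, a fatty acid desaturase, dropped 1.7-fold from 961.5 ± 67.6 to 564.7 ± 43 CPM (adjusted p = 7.28e-05), Fads2 1.39-fold (adjusted p = 8.84e-07) and Fasn, the fatty acid synthase, 1.35-fold (adjusted p = 2.97e-09), while Scd1 rose 1.07-fold (adjusted p = 0.0229, but 0.062 without L6, 0.0634 without both libraries numbered 6, 0.0912 with offsets for GC content and length and 0.0936 with library totals alone). The regulators themselves were lower, Srebf2 by 1.48-fold from 249.8 ± 8.45 to 168.4 ± 1.33 CPM (adjusted p = 5.49e-10) and Srebf1 by 1.25-fold (adjusted p = 1.03e-06). Genes of class I antigen presentation fell beside the interferon response, with 13 of 15 lower and a median log2 fold change of -0.26 (camera adjusted p = 5.77e-10, and adjusted p = 0.0099 with an estimated correlation). Tap1 and Psmb8 are members of both of these lists. Others were Psmb9 (1.36-fold, adjusted p = 0.00062), H2-Q4 (1.33-fold, adjusted p = 1.64e-05) and Nlrc5, an activator of this gene class (1.3-fold, adjusted p = 0.0012). Set p-values were adjusted over 6 lists here and over 29 for the planned lists, so the adjusted values are not comparable. The fatty acid and class I lists, like the epidermal growth factor receptor and actin lists below, were also chosen after gene values were seen. Their p-values, adjusted or not, are thus only descriptive and cannot be ranked against those of planned lists. Unadjusted, camera with an estimated correlation gave p = 0.015 for fatty acid synthesis and 0.0017 for class I genes. It gave 0.0049 for the planned interferon response list and 0.0076 for that of cholesterol synthesis.

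Ligands and feedback genes of the epidermal growth factor receptor were higher, with 7 of 13 up and 2, Nrg1 and Lrig1, down (median log2 fold change 0.32, camera adjusted p = 0.000379, and adjusted p = 0.142 with an estimated correlation; median 0.205 without C7). Ereg rose 1.69-fold from 218.4 ± 17.4 to 369.3 ± 15.8 CPM (adjusted p = 1.01e-07), Hbegf 1.68-fold (adjusted p = 2.1e-08), Areg 1.44-fold (adjusted p = 3.4e-05) and the receptor inhibitor gene Errfi1 1.45-fold (adjusted p = 7.09e-10). Genes of the actin cytoskeleton and cell adhesion rose in 16 of 20 members (median log2 fold change 0.18, camera adjusted p = 2.89e-11, and adjusted p = 0.0725 with an estimated correlation), among them the integrin gene Itga5 (1.55-fold, adjusted p = 1.15e-05), Myh9 (1.2-fold, adjusted p = 6.32e-06) and Zyx (1.13-fold, adjusted p = 0.000226). Csf1, the ligand of the receptor encoded by Csf1r, rose 1.35-fold from 2249 ± 80.7 to 3034 ± 123 CPM (adjusted p = 9.1e-09), and Il11 1.45-fold (adjusted p = 3.74e-06). Nrg1 lost its call without C8, L5 or L8 (adjusted p up to 0.0582, without C8).

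The drop in cholesterol synthesis genes was set against bias and against how the dishes were handled. Bias from transcript length and GC content is argued against, since the list's median log2 fold change was -0.69 with offsets for both. The medium was removed before irradiation per the labels' protocols, which do not say how the controls were treated. A candidate explanation is renewed serum or growth factor supply in the irradiated dishes, which would lower FOXO targets: their median log2 fold change was -0.19 (18 genes, 6 lower and 2, Btg1 and Klf9, higher; camera adjusted p = 0.0127 over the 6 lists), with Irs2, Sesn1 and Ccng2 lower by 1.6-fold, 1.5-fold and 1.47-fold, though the set lost its call with an estimated correlation (adjusted p = 0.0653) and without both libraries numbered 6 (0.0525), which leaves this open. A sterol surplus would raise LXR targets, and 3 of 9 were higher and 0 lower, with a median of 0.072 (mean -0.008, camera adjusted p = 0.181 over the 6 lists). The set passed with DESeq2 and with 0 of the other 21 alternatives, which leaves that open too, and the design does not separate an effect of the laser itself from handling.

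For the interferon response genes the technical explanations considered were length and GC bias, and scaling between libraries. With offsets for the first, the list's median log2 fold change was -0.27. Length and GC bias is thus argued against as the cause. Relative to the median of all tested genes the list's median was -0.26 or lower under 4 scalings. A scaling moves all genes by about the same amount, which that reference removes, so these values could hardly differ and do not test scaling. They show that the list fell against the typical gene. Without that reference its median ran from -0.29 to -0.26 over 22 alternatives, other scalings among them. An effect of irradiation or of handling remains as a hypothesis that these data do not separate.

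Relative to the mean of all 8 libraries, expression changed by 0.0323, 0.0058, 0.036 and 0.0144 log2 units per doubling of transcript length in L5 to L8. In C5 to C8 the slopes were -0.014, 0.0212, -0.0381 and -0.0577, so C6 lay within the irradiated range. The most abundant feature without a symbol, ENSMUSG00000119584.1, took 0.254% to 0.328% of counts in non-irradiated and 0.199% to 0.24% in irradiated libraries.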
